A study of Mus musculus with 12 samples.

How the data were processed

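Total RNA from 12 samples labelled Hepa1-6 was sequenced, and per the labels 3 samples each were untreated or given IFNa, antiPD1 or both. Groups were taken from the sample labels and columns were matched to samples by their names. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq and Cufflinks were used with the mm10 assembly; the annotation, the strand setting and the step each tool served are not given in the sources used here. The deposited count table holds 1 integer count per gene and library, and the deposited FPKM table holds fragments per kilobase and M fragments for the same genes and libraries. No other sample's columns were present.

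The count table had 21878 genes. Library totals ranged from 31.3 to 38.5 M (mega), the 50 most abundant genes held 12.5% to 16.7% of each total, and the tested genes held at least 99.97%. A count of 3 corresponded to 0.0916 to 0.102 CPM (counts per M) in untreated libraries, and this was used as the floor below which no fold is given. Floors and standard errors cover counting error and the spread between these libraries only. All 12 libraries were kept as separate samples. Gene symbols were compared with GENCODE M21, where 20665 of 21878 (94.5%) matched, and coordinates are from that release.

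Groups, comparisons, gene lists and alternatives were fixed before the data were examined. R 4.3.3 was used. Genes were filtered with filterByExpr (minimum count 10), scaled with TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16, with all 12 libraries and 1 mean per group, for 6 pairwise comparisons and the interaction of IFNa and antiPD1. P-values were adjusted by Benjamini-Hochberg over 14330 genes with a threshold of 0.05. Gene lists (35 lists, 572 genes, written from general knowledge) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and adjusted over 35 lists. Each list was also tested with a correlation estimated from the data and with the rotation test fry. Member genes were counted as risen or fallen over all genes, and also with p-values adjusted over the list alone. CPM values are means with SD of TMM-scaled counts.

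Genes are named in the report by a fixed rule: up to 6 rises and 6 falls with the largest fold among genes that passed, had at least 5 CPM in the higher group and did not overlap between groups; up to 4 members of lists that passed; and 16 genes chosen in advance. Where no gene passed, the 3 smallest p-values in each direction are given. From each set the text gives examples. Genes with near-identical copies share reads and are described as uncertain.

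Alternatives tried were RLE size factors, no low-count filter, a minimum of 2-fold, only the groups compared, DESeq2 1.42.0, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM with a minimum FPKM of 1 in 3 libraries, the former without a filter, and leaving out each library. Only the interaction could not be fitted to the groups compared alone, because it needs all 4. After the data were seen, 2 alternatives were added: IFNa replicate 1 and antiPD1 replicate 3 left out together, and the mean log2 CPM of Ddx3y, Eif2s3y, Kdm5d and Uty per library as a covariate. Fold changes of comparisons that share the untreated libraries were set against 20 simulations in which only the shared libraries link them. Regroupings of the libraries between groups were counted for each comparison.

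The procedure was tested on simulated data with 200 changed genes per comparison. edgeR recovered 38.0% to 50.5% of 2-fold and 68.7% to 83.0% of 4-fold changes in pairwise comparisons, with 4 to 10 false calls, and 23.5% and 57.6% with 2 false calls in the interaction. DESeq2 made 48 and 47 false calls in the 2 comparisons where it was tried, so it was kept as an alternative. A list lowered on purpose passed in both comparisons with the preset and the estimated correlation. Of 34 other lists, 2 passed in 1 comparison with the preset correlation and 0 in the other tests. Genes were drawn independently in these simulations, and no library was made outlying. The simulations therefore cannot show how often the preset correlation gives false calls where members of a list vary together. Mx1, Mx2, Cxcl11 and the constant genes of T cell receptors and immunoglobulin M were not analysed here.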

Results

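Gene expression was measured by RNA sequencing of total RNA in 12 libraries labelled as Hepa1-6, a mouse hepatoma cell line, with liver as the tissue. There were 4 groups of 3 libraries: untreated, IFNa (interferon alpha), antiPD1 (an antibody against the checkpoint receptor PD-1) and the combination of both. Each library held 31.3 to 38.5 M (mega) counted reads, 15678 to 16377 of 21878 genes had at least 1 count, and 14330 genes were tested. Hepatoma transcripts were abundant in every group: Afp, the fetal serum protein alpha-fetoprotein, had 10413 ± 696 CPM (counts per M, mean ± SD, n = 3 throughout) in untreated, 9748 ± 1768 in IFNa, 7019 ± 666 in antiPD1 and 6129 ± 687 in combination libraries. Immune cell transcripts were also present, such as the T cell co-receptor Cd8a (5.57 ± 0.272 CPM in untreated libraries) and the macrophage lysozyme Lyz2 (76.3 ± 50.7 CPM). Summed expression of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) was 14.1 ± 6.74 CPM in untreated, 20.3 ± 6.21 in IFNa, 53.3 ± 36.2 in antiPD1 and 40.5 ± 10.8 in combination libraries. The first principal component carried 53.7% of the variance and separated untreated libraries (-73.7, -72.1 and -22.6) from combination libraries (24.7 to 56.5). The libraries furthest from their own group were antiPD1 replicate 3 (91.9 on the first component, against 22.9 and 10.8) and IFNa replicate 1 (-70.6 on the second, against 11.4 and 15.0). Errors beside log2 fold changes are standard errors. The p-values of single genes measure only the spread between these samples, because the labels do not say whether replicates came from separate animals or cultures. List p-values compare the genes of a list with the other genes. With the preset correlation of 0.01 they do not take up how far list members varied together in these libraries. The values marked as estimated do so.

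IFNa was compared with untreated libraries as the effect of IFNa alone. No single gene passed over all 14330 genes, but the type I interferon response genes were higher as a group. Their median log2 fold change was 0.51 with 34 of 36 members higher (adjusted p = 3.4e-18, adjusted p = 0.869 with an estimated correlation), and 10 members passed when p-values were adjusted over the list alone. The member with the smallest p was Ifit1, an antiviral RNA-binding protein (2.40 ± 0.945 to 6.17 ± 1.68 CPM; log2 fold change 1.36 ± 0.30, adjusted p = 0.749). Ifi44, another interferon-induced antiviral gene, had 4.84 ± 0.750 and 9.83 ± 2.07 CPM, and the ubiquitin-like modifier Isg15 had 6.88 ± 1.57 and 11.9 ± 2.71 (0.79 ± 0.24, adjusted p = 0.866). Ifit1 and other Ifit genes resemble each other in sequence, so their separate values are uncertain. The list median was 0.31 without untreated replicate 1.

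The other genes with the smallest p-values in this comparison were Rsrp1, an arginine and serine rich protein of splicing speckles (46.4 ± 2.91 to 84.8 ± 21 CPM), and the lymphocyte growth regulator Slfn1 (3.10 ± 1.19 to 6.87 ± 0.485). Lower values were seen in the Wnt inhibitor Notum (168 ± 72.2 to 46.4 ± 14.2 CPM, log2 fold change -1.85 ± 0.35), the vasopressin receptor Avpr1a (203 ± 68.8 to 82.0 ± 18.1; -1.31 ± 0.26) and the lipid transfer domain protein Stard13 (53.1 ± 4.77 to 25.6 ± 3.21; -1.06 ± 0.20), each with an adjusted p of 0.749. edgeR called 0 genes with 801 at an unadjusted p below 0.05, limma called 0 and DESeq2 called 37, among them Notum, Stard13, Avpr1a, Slfn1, Ifit1, Rsrp1 and Ifi44. Pancreatic acinar genes, found mainly in 4 libraries, made up 2 of these 37. The 3 IFNa values did not overlap the 3 untreated values in 10.2% of genes, where 10% would arise by chance.

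Of 35 gene lists, 11 were higher and 3 lower after IFNa with the preset correlation, and 0 with an estimated one. The 18 cholesterol synthesis genes were all lower (median -0.33, adjusted p = 6.6e-07, 0.928 estimated), for example the squalene epoxidase Sqle (331 ± 53.1 to 227 ± 6.11 CPM). This median was -0.53, -0.19 and -0.21 without IFNa replicates 1, 2 and 3. Cell cycle genes were lower in 28 of 29 members (median -0.33, adjusted p = 3.6e-09, 0.928 estimated), but the median was -0.08 without IFNa replicate 1 and no longer passed. Fibroblast and matrix genes were higher in 18 of 18 members (median 0.46, adjusted p = 4.1e-06, 0.928 estimated), with 0.14 and no call without untreated replicate 2, 0.30 without untreated replicate 1 and 1.07 without untreated replicate 3. T cell markers did not pass (median 0.36, adjusted p = 0.217), but did so with a median of 0.72 when IFNa replicate 1 and antiPD1 replicate 3 were left out (adjusted p = 1.1e-07), a setting chosen after the data were seen. Only the type I interferon and cholesterol lists, 2 of 14, kept their call without every single library, and no member of any of these lists passed over all genes.

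Leaving out IFNa replicate 1 brought 3 genes through the test, and these lie near each other on chromosome 17. They were the G protein-coupled receptor relative Gpr108 (log2 fold change 0.96, adjusted p = 0.0187), the endocytosis adaptor Trip10 (1.42, 0.0308) and the NAD-cap hydrolase Nudt12 (1.24, 0.0308). With antiPD1 replicate 3 also left out, the polarity protein Crb3 (1.15, adjusted p = 0.00625) and complement component C3 (1.38, 0.0131) passed as well. Trip10 had 114, 334 and 338 CPM in IFNa replicates 1, 2 and 3 against an untreated mean of 125, and C3 had 3609, 12855 and 9842 against 4445. These 5 genes span 1.95 Mb from Crb3 (57059105) to Nudt12 (59013372; mm10, GENCODE M21) and were 1.02 to 1.53 log2 above the median of the 10 other libraries in both IFNa replicates 2 and 3. The 5 neighbouring genes on each side had medians of 0.02 and -0.03. The other 3 genes of at least 5 CPM in the interval, the leukocyte genes Dennd1c, Vav1 and Adgre1, followed the leukocyte phosphatase Ptprc (r of 0.965 to 0.985). They were set aside. Crb3 overlaps the ends of its neighbours, so its value is uncertain. The interval was found by searching the genome after IFNa replicate 1 had been left out.

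**Figure D1:**
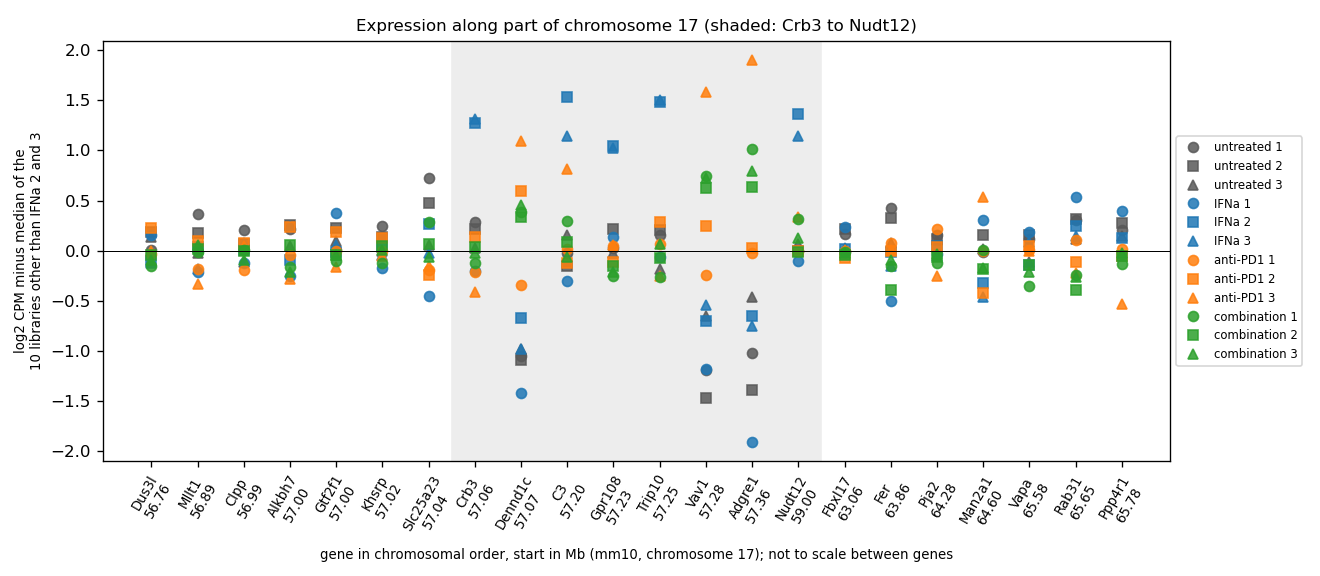
Genes in order along part of chromosome 17 (horizontal, starts in Mb, not to scale). The vertical axis is log2 CPM minus the median of the 10 libraries other than IFNa replicates 2 and 3. Each point is 1 gene in 1 of the 12 libraries. The shaded interval from Crb3 to Nudt12 holds 8 genes. Of these, 5 were at 1.02 to 1.53 in IFNa replicates 2 and 3. The leukocyte genes Dennd1c, Vav1 and Adgre1 were negative in both (-0.98 to -0.55).

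antiPD1 was compared with untreated libraries as the effect of antiPD1 alone, and genes of many immune cell types rose. Of 21 T cell markers, 19 rose (20 adjusted over the list alone, median log2 fold change 2.50, adjusted p = 1.3e-12, adjusted p = 0.273 with an estimated correlation). Without antiPD1 replicate 3 the T cell median was 1.71 and 2 of 21 rose. Cd8a, the co-receptor of cytotoxic T cells, rose from 5.57 ± 0.272 to 25.8 ± 14.7 CPM (2.21 ± 0.44, adjusted p = 0.0204). Cd5, a damping co-receptor of T cells, rose by 2.63 ± 0.50 and Bcl11b, a T cell transcription factor, by 2.92 ± 0.58. Cytotoxic effector genes rose in 13 of 14 members (14 over the list alone, median 2.14, adjusted p = 1.8e-08, 0.273 estimated), including the cytokine Ifng (0.514 ± 0.0582 to 3.12 ± 1.58 CPM) and the granule protease Gzmk (2.92 ± 0.63). The granule protease Gzmb did not pass (7.32 ± 1.03 and 15.1 ± 8.29 CPM, adjusted p = 0.0725). Checkpoint genes rose in 11 of 14 members (13 over the list alone, median 1.92, adjusted p = 3.3e-08, 0.273 estimated), among them the target of the antibody, Pdcd1 (2.22 ± 0.220 to 13.5 ± 10.3 CPM, log2 fold change 2.60 ± 0.60), and the exhaustion receptor Havcr2 (2.05 ± 0.43). The PD-1 ligand Cd274 rose by 1.75 ± 0.43 (27.1 ± 8.50 to 91.3 ± 66.0 CPM) and the T cell costimulator Cd27 by 2.32 ± 0.60. Regulatory T cell markers rose in 5 of 8 (8 over the list alone, median 2.46, 0.273 estimated), such as their defining factor Foxp3 (0.457 ± 0.191 to 2.81 ± 2.71 CPM). Without antiPD1 replicate 3 the regulatory T cell median was 1.53 and Foxp3 did not pass (1.5, adjusted p = 0.134). The checkpoint median was then 1.15, and Cd274 was 0.98 and no longer passed (adjusted p = 0.0703).

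B and plasma cell markers rose in 9 of 11 members (10 over the list alone, median 2.53, adjusted p = 1.3e-12, 0.273 estimated). The antibody joining chain Jchain had the smallest p of the 9, from 1.69 ± 0.522 to 40.0 ± 17.6 CPM (4.56 ± 0.42, adjusted p = 0.00259), and the B cell receptor subunit Cd79b rose by 2.65 ± 0.40. Macrophage and monocyte markers rose in 17 of 21 members (20 over the list alone, median 1.80, adjusted p = 7.2e-12, 0.273 estimated), for example the Fc receptor Fcgr1 (1.77 ± 0.34), the integrin Itgam (2.34 ± 0.49) and Lyz2 (76.3 ± 50.7 to 997 ± 1069.9 CPM, log2 fold change 3.71 ± 0.78). Without antiPD1 replicate 3 the macrophage median was 1.09 with 2 of 21 rising, and Lyz2 was 2.32 and no longer passed (adjusted p = 0.0531). Neutrophil markers rose in 7 of 14 members (11 over the list alone, median 1.95), including the chemokine receptor Cxcr2 (1.89 ± 0.30) and the calcium-binding alarmin S100a9 (1.99 ± 0.39), and dendritic cell markers in 6 of 13 (13 over the list alone, median 1.82), both with 0.273 estimated. Mast cell markers rose in 5 of 6 members (6 over the list alone, 0.273 estimated) from levels at or below the 3-count floor of 0.0916 to 0.102 CPM. The mast cell protease Mcpt4 had 0.0871 ± 0.0419 and 1.21 ± 0.538 CPM, so its fitted fold depends on the prior count. NK cell markers rose in 3 of 8 members (4 over the list alone, median 1.66, adjusted p = 0.0364, 0.306 estimated), and lost the call without untreated replicate 3, antiPD1 replicate 2 or antiPD1 replicate 3 (adjusted p = 0.145, 0.0933 and 0.0770).

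Antigen presentation and interferon genes rose with them. MHC class II genes rose in 10 of 11 members (11 over the list alone, median 2.28, adjusted p = 8.2e-08, 0.273 estimated), such as the peptide-loading subunit H2-DMa (1.64 ± 0.35, and 1.07 without antiPD1 replicate 3), and MHC class I genes in 12 of 19 (18 over the list alone, median 0.95, 0.61 without antiPD1 replicate 3, 0.273 estimated). H2-K1, a classical class I chain, rose by 2.68 ± 0.52, and by 1.68 without that library. Type I interferon genes rose in 12 of 36 members (23 over the list alone, median 0.76, adjusted p = 2.1e-08, 0.273 estimated), for example the oligoadenylate synthetase relative Oasl2 (18.3 ± 6.83 to 48.4 ± 8.87 CPM, log2 fold change 1.41 ± 0.27). Without antiPD1 replicate 3 the list median was 0.56 and 0 of 36 rose. With the Y-linked level as a covariate it was 0.15 (adjusted p = 0.0288) and 0 of 36 rose. Interferon gamma inducible GTPases and IRF1 targets rose in 11 of 22 (16 over the list alone, median 1.23, adjusted p = 6.4e-11, 0.273 estimated). Of the T cell recruiting chemokines 7 of 8 rose (8 over the list alone, median 1.75, 0.273 estimated), including Ccl3 (1.63 ± 0.29), Cxcl10 (1.40 ± 0.42) and Cxcl9 (51.4 ± 20.4 to 333 ± 287 CPM, log2 fold change 2.70 ± 0.61). Cxcl9 was 1.72 and did not pass without antiPD1 replicate 3 (adjusted p = 0.0712), and Isg15 did not pass with all libraries (0.74 ± 0.24, adjusted p = 0.0598).

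Stromal and hepatocyte genes gave a less even picture. Fibroblast and matrix genes rose in 6 of 18 members (16 over the list alone, median 1.30, adjusted p = 1.8e-08, 0.273 estimated), including the platelet-derived growth factor receptor Pdgfrb (1.28 ± 0.36). Endothelial markers were higher with 0 of 12 passing (median 0.96, adjusted p = 0.0138, 0.577 estimated), and lost the call without untreated replicate 1 (0.72), antiPD1 replicate 1 (0.56) and antiPD1 replicate 3 (0.87), with 1.66 without untreated replicate 3. The 17 adult hepatocyte enzymes were all higher with 0 passing alone (median 2.23, adjusted p = 0.00142, 0.531 estimated), and the median was 0.58 with no call without antiPD1 replicate 3. With the Y-linked level as a covariate, the medians of the endothelial and adult hepatocyte lists turned negative. The urea cycle enzyme Arg1 did not pass (25.4 ± 19.5 and 184 ± 149 CPM, adjusted p = 0.0745). The largest rises of single genes were in acute phase and liver genes: the serum amyloids Saa2 (3.80 ± 3.16 to 579 ± 684 CPM, log2 fold change 7.26 ± 1.01) and Saa3 (1.78 ± 0.745 to 196 ± 242; 6.78 ± 0.97). The urinary pheromone carrier Mup14 (0.0221 ± 0.0191 to 22.3 ± 36.4 CPM), the organic anion carrier Slco1a1 (0.0324 ± 0.0562 to 12.1 ± 17) and the fatty acid elongase Elovl3 (0.0544 ± 0.0207 to 9.33 ± 13.9) started below the floor, so no fold is given. Mup14 and Elovl3 did not pass without antiPD1 replicate 3 (adjusted p = 0.116 and 0.0973). Saa2 and Mup14 have near-identical copies, as do Cyp2a4 and Cyp3a16 below, and their values are uncertain.

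Several single genes fell with antiPD1, liver genes among them. The steroid hydroxylase Cyp2a4 fell by 6.07 ± 0.73 (139 ± 109.7 to 2.06 ± 0.725 CPM), the drug-metabolising Cyp3a16 by 3.64 ± 0.56, the ferlin membrane protein Fer1l6 by 3.12 ± 0.64 and the progesterone-metabolising Akr1c18 by 2.98 ± 0.51. Among hepatocyte and hepatoma genes Afp fell by 0.57 ± 0.14 and the liver transcription factor Hnf4a by 0.65 ± 0.18. The lipoprotein Apoa2 rose by 2.50 ± 0.72 (1.37 without antiPD1 replicate 3, adjusted p = 0.185). The list did not pass (adjusted p = 0.251). Cholesterol synthesis genes fell in 4 of 18 members (4 over the list alone, median -0.33, adjusted p = 0.00105, 0.444 estimated). This median was -0.18 without antiPD1 replicate 2 and -0.52 without replicate 3. Of 29 cell cycle genes the mitotic cyclin Ccnb1 (-0.88 ± 0.25) and the mitotic activator Cdc20 (-0.76 ± 0.22) fell (0 over the list alone, median -0.44, 0.495 estimated). Hypoxia and glycolysis lists did not pass (medians -0.08 and -0.04), and the glucose transporter Slc2a1 (-0.18 ± 0.18), the glycolytic enzymes Hk2 (0.13 ± 0.13) and Ldha (-0.25 ± 0.11) and the hypoxia factor Hif1a (0.20 ± 0.15) did not pass.

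In total 1398 genes rose and 728 fell after antiPD1, and 36.0% of genes had non-overlapping values (10% by chance). The number of calls rested on single libraries: 5 genes without untreated replicate 1, 6 without untreated replicate 2 and 328 without antiPD1 replicate 3. Of 103 named genes that passed, 2, 2 and 29 still did so, and none changed direction. A fit of only the groups compared called 0 genes, and 19 of 22 called lists kept their call without every single library.

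**Figure D2:**
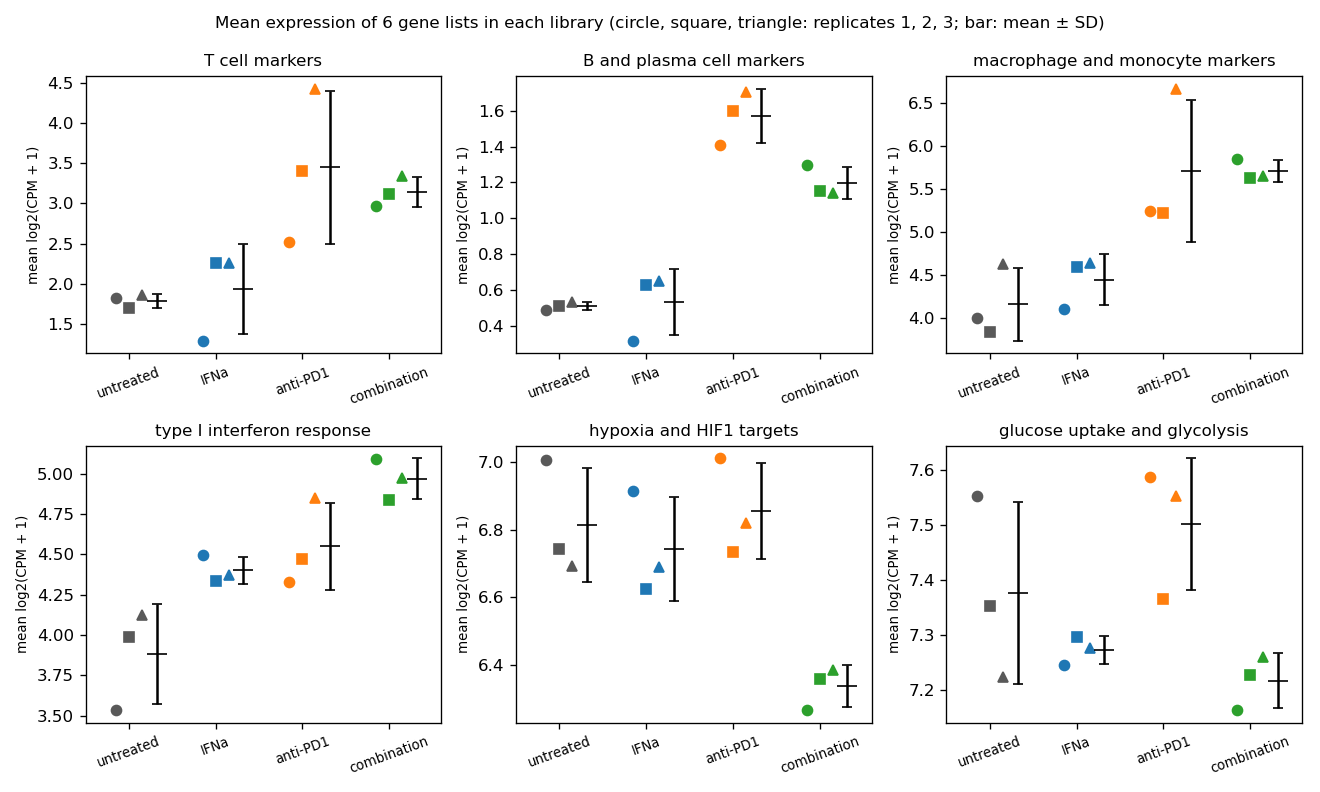
Mean log2(CPM + 1) of the genes of 6 lists (vertical) in each of the 4 groups (horizontal); each point is 1 library. T cell scores are highest in antiPD1 and combination libraries, with a median log2 fold change of 2.50 for antiPD1 against untreated, and hypoxia scores are lowest in the combination.

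The combination was compared with untreated libraries as the effect of both treatments together. Interferon genes rose: 25 of 36 type I interferon genes passed (30 over the list alone, median 1.12, adjusted p = 4.2e-20, adjusted p = 0.275 with an estimated correlation). With the Y-linked level as a covariate the list kept its call at a median of 0.67, and 0 of 36 passed. Oasl2 rose from 18.3 ± 6.83 to 78.3 ± 11.1 CPM (2.1 ± 0.28), Ifit1 from 2.40 ± 0.945 to 10.8 ± 1.96 (2.17 ± 0.30), the ADP-ribosyltransferase Parp14 from 56.3 ± 16.5 to 138 ± 9.50 (1.30 ± 0.19) and Isg15 from 6.88 ± 1.57 to 18.4 ± 2.45 (1.42 ± 0.24, adjusted p = 0.0134). Interferon gamma inducible GTPases and IRF1 targets rose in 16 of 22 members (19 over the list alone, median 1.60, adjusted p = 6.0e-15, 0.333 estimated), including the cytokine signalling inhibitor Socs1 (1.57 ± 0.32). MHC class I genes rose in 11 of 19 (16 over the list alone, median 0.85) and MHC class II genes in 5 of 11 (11 over the list alone, median 2.08), both 0.333 estimated, such as the class I activator Nlrc5 (1.20 ± 0.24) and the class II activator Ciita (2.14 ± 0.53). T cell recruiting chemokines rose in 6 of 8 (8 over the list alone, median 1.98, 0.327 estimated), among them Cxcl10 (21.1 ± 8.24 to 88.9 ± 24.8 CPM, log2 fold change 2.08 ± 0.42) and Cxcl9 (2.12 ± 0.60).

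Immune cell markers rose here too. T cell markers rose in 8 of 21 members (19 over the list alone, median 1.90, adjusted p = 2.6e-09, 0.333 estimated), with Cd8a at 19.96 ± 2.31 CPM (1.84 ± 0.44) and Cd5 at 4.66 ± 0.786 (2.06 ± 0.50). Cytotoxic effector genes rose in 5 of 14 (11 over the list alone, median 1.83, 0.333 estimated), such as Ifng (2.57 ± 0.52) and the transcription factor Tbx21 (2.68 ± 0.70), while Gzmb stayed at 6.97 ± 1.43 CPM. Checkpoint genes rose in 5 of 14 (10 over the list alone, median 1.40, 0.333 estimated), including Pdcd1 (2.29 ± 0.60). Cd274 (1.44 ± 0.43, adjusted p = 0.0503) and Cd27 (1.92 ± 0.59, adjusted p = 0.0557) did not pass. Macrophage markers rose in 13 of 21 (18 over the list alone, median 1.73, adjusted p = 2.8e-11, 0.333 estimated), for example the monocyte chemokine receptor Ccr2 (1.85 ± 0.44), and neutrophil markers in 7 of 14 (12 over the list alone, median 2.09, 0.275 estimated), such as the gelatinase Mmp9 (2.42 ± 0.47). B and plasma cell markers rose in 4 of 11 (9 over the list alone, median 1.85, 0.275 estimated), with Jchain at 24.0 ± 3.17 CPM (3.82 ± 0.41). Mast cell markers rose in 5 of 6 (5 over the list alone, 0.221 estimated), for example Mcpt4 from 0.0871 ± 0.0419 to 3.51 ± 1.59 CPM, with untreated values below the floor. NK cell markers did not pass (adjusted p = 0.299). Fibroblast genes passed as a list with 0 of 18 members alone (5 over the list alone, median 0.83, 0.375 estimated), and their median was 0.55 without untreated replicate 2 and 1.5 without untreated replicate 3.

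Hypoxia and glucose genes fell with the combination. Of 21 hypoxia and HIF1 targets 9 fell (12 fell and 1 rose over the list alone, median -0.55, adjusted p = 3.0e-06, 0.275 estimated): Slc2a1 fell from 427 ± 108 to 220.0 ± 26.0 CPM (-0.96 ± 0.18, adjusted p = 0.0162), the stress-response gene Ndrg1 by 1.13 ± 0.22, the angiogenic factor Vegfa by 0.63 ± 0.14 and the oxygen-sensing hydroxylase Egln3 by 0.69 ± 0.16. Glycolysis genes fell in 4 of 23 members (5 over the list alone, median -0.28, adjusted p = 0.00242, 0.375 estimated), including phosphofructokinase Pfkm (-0.61 ± 0.12) and lactate dehydrogenase Ldha (2712 ± 398 to 1982 ± 48.3 CPM, log2 fold change -0.45 ± 0.11). With the Y-linked level as a covariate the glycolysis list lost its call (-0.14, adjusted p = 0.134). The hypoxia list kept its call (-0.46, adjusted p = 2.4e-04), and 0 members of either list fell. Hif1a (-0.10 ± 0.15) and Hk2 (-0.25 ± 0.13) did not pass. Hepatocyte and hepatoma genes fell in 4 of 24 (7 fell and 1 rose over the list alone, median -0.36, 0.375 estimated), such as Afp (-0.76 ± 0.14) and keratin Krt18 (-0.58 ± 0.10). Of 18 immediate early genes 3 fell and 1 rose (6 and 1 over the list alone, median -0.59, 0.459 estimated), among them the growth-responsive factor Egr1 (213 ± 120.3 to 55.9 ± 8.51 CPM) and the growth regulator Myc (-0.84 ± 0.23). The immediate early call was lost without untreated replicate 3 (-0.38, adjusted p = 0.160), and Fosb did not pass (16.4 ± 12.4 and 6.04 ± 0.412 CPM). The largest falls were in Cyp2a4 (to 1.07 ± 0.474 CPM, log2 fold change -7.01 ± 0.77) and the squamous envelope protein Ivl (27.0 ± 15.6 to 1.56 ± 0.381; -4.11 ± 0.53). The largest rises above the floor were in Saa2 (to 555 ± 261 CPM, log2 fold change 7.20 ± 1.01) and Saa1 (6.42 ± 4.69 to 595 ± 278; 6.54 ± 0.92).

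In total 1086 genes rose and 717 fell with the combination, and 49.5% of genes had non-overlapping values (10% by chance). Of called genes 60.2% were higher, against 37.1% to 63.6% when 1 library was left out, 52.2% with only the groups compared and 79.8% to 83.0% with limma on FPKM. Calls numbered 33 to 207 when any 1 library other than untreated replicate 3 was left out, and 2594 without untreated replicate 3. Of 96 named genes that passed, 11 still did so without combination replicate 3, 15 without untreated replicate 1, 19 without untreated replicate 2, 21 without combination replicate 2 and 28 without combination replicate 1, all in the same direction. Of 25 called lists, 19 kept their call without every single library.

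Both groups given antiPD1 changed many of the same genes against the shared untreated libraries: 861 rose in both, 391 fell in both and 0 went opposite ways. Saa2 and Jchain were among the shared rises and Cyp2a4 among the shared falls. The log2 fold changes of antiPD1 and the combination correlated at 0.881, where simulations with only the shared controls gave 0.505, and their covariance was 0.728 against 0.0779. IFNa and the combination gave 0.564 against 0.507 (covariance 0.249 against 0.0777), and IFNa and antiPD1 0.682 against 0.507 (0.328 against 0.0777). The 3 untreated libraries cannot be divided between the comparisons, so part of each excess may come from those libraries.

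The combination was compared with antiPD1 as the effect of adding IFNa to antiPD1. No gene passed, but hypoxia and HIF1 targets were lower in 20 of 21 members, and this list was the only one that also passed with an estimated correlation (median -0.50, adjusted p = 1.1e-20, 0.0445 estimated, 5 members fell over the list alone). The rotation test fry called 0 lists. The collagen prolyl hydroxylase P4ha1 had 146 ± 8.84 CPM with antiPD1 and 103 ± 13.4 with the combination (-0.50 ± 0.10), Vegfa 618 ± 57.2 and 379.8 ± 46.5 (-0.70 ± 0.14), Ndrg1 517 ± 75.5 and 268 ± 29.7, and Slc2a1 375 ± 5.28 and 220.0 ± 26.0 (-0.77 ± 0.18, adjusted p = 0.991). Glycolysis genes were lower in 22 of 23 members (median -0.28, adjusted p = 1.5e-11, 0.200 estimated, 2 fell over the list alone), with Hk2 at 391 ± 64.0 and 301 ± 27.3 CPM. Type I interferon genes were higher in 34 of 36 (median 0.42, adjusted p = 3.3e-15, 0.228 estimated, 0 over the list alone), with Ifit1 at 5.20 ± 0.212 and 10.8 ± 1.96 CPM, and the median was 0.26 without antiPD1 replicate 1. All 29 cell cycle genes were higher (median 0.28, adjusted p = 6.9e-08, 0.583 estimated) and all 11 B and plasma cell markers lower (median -0.69, adjusted p = 6.5e-07, 0.228 estimated). Immediate early genes were lower (median -0.67, adjusted p = 4.3e-10, 0.200 estimated), and -0.39 without antiPD1 replicate 3.

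Several immune cell lists in this comparison depended on antiPD1 replicate 3. T cell markers had a median of -0.59 (adjusted p = 0.00223, 0.722 estimated), but 0.14 and no call without that library (adjusted p = 0.256), -0.52 and no call without combination replicate 1 (adjusted p = 0.0626), and -0.99 without antiPD1 replicate 1. Checkpoint genes turned from -0.33 (adjusted p = 0.0216, 0.722 estimated) to 0.30 without antiPD1 replicate 3, -0.33 with no call without combination replicate 1, -0.60 without antiPD1 replicate 1 and -0.54 without antiPD1 replicate 2. Macrophage markers turned from -0.26 with no call (adjusted p = 0.525) to 0.55 with a call without antiPD1 replicate 3 (adjusted p = 1.5e-08). Mast cell markers were higher in the combination (median 1.56, adjusted p = 8.5e-05, 0.200 estimated) and were 1.95 without that library. Gzmb had 15.1 ± 8.29 and 6.97 ± 1.43 CPM (adjusted p = 0.997). The genes with the smallest p-values were the myelin protein Pllp (19.6 ± 1.96 to 33.6 ± 4.02 CPM), the lung chemokine Cxcl15 (15.9 ± 6.44 to 39.5 ± 7.10), the death receptor inhibitor Faim2 (7.69 ± 6.31 to 114 ± 32.6), the arginase Arg2 (37.1 ± 3.99 to 22.5 ± 1.82) and the kinesin Kif21b (48.9 ± 6.41 to 30.3 ± 1.76). edgeR and limma called 0 genes (682 at an unadjusted p below 0.05), and DESeq2 called 15, including Arg2, Pllp, Vegfa, P4ha1 and Ndrg1. The smallest DESeq2 adjusted p was that of Cyp2c69, and 2 of the 15 are pancreatic acinar genes found mainly in 4 libraries. DESeq2 made 47 false calls in the simulation of this comparison, so its 15 calls add little. In this comparison 14.2% of genes had non-overlapping values (10% by chance). Of 21 called lists 8 kept their call without every single library, among them hypoxia, glycolysis, type I interferon, cell cycle, and B and plasma cell lists.

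**Figure D3:**
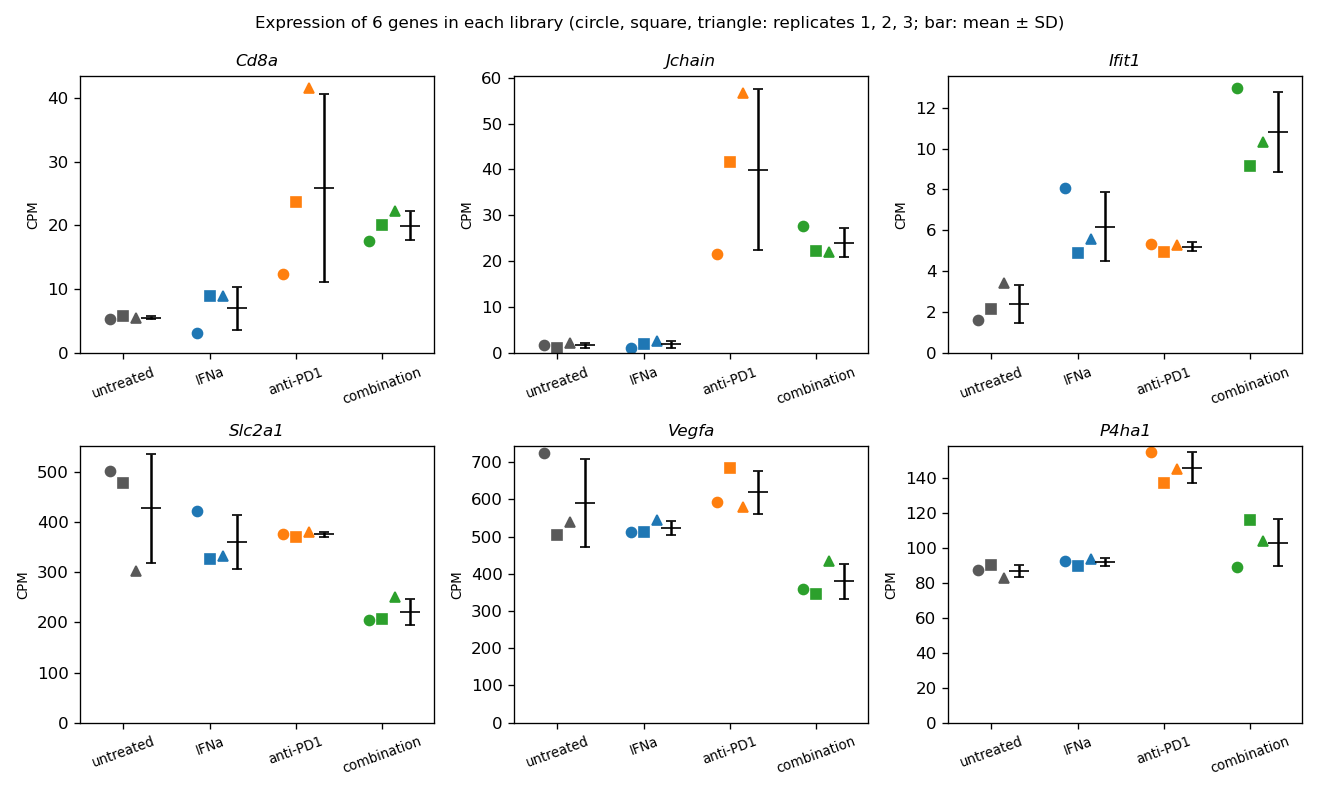
CPM (vertical) of 6 genes in the 4 groups (horizontal); each point is 1 library. Jchain averages 40.0 in antiPD1 and 1.69 in untreated libraries, and Slc2a1 averages 220.0 in the combination and 427 in untreated libraries.

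The combination was compared with IFNa as the effect of adding antiPD1 to IFNa, and 49 genes rose and 88 fell. Jchain rose from 1.92 ± 0.751 to 24.0 ± 3.17 CPM (3.64 ± 0.41, adjusted p = 0.0105), the lysophosphatidic acid producing enzyme Enpp2 from 15.9 ± 1.45 to 73.8 ± 7.77 (2.22 ± 0.25) and the death ligand Tnfsf10 from 4.57 ± 1.12 to 17.5 ± 1.17 (1.93 ± 0.34). The T cell adaptor Grap2 (1.89 ± 0.35) and the iron-binding neutrophil protein Ltf (2.19 ± 0.43) rose, and the epithelial protease Prss22 (-2.90 ± 0.35), Ivl (-3.14 ± 0.51) and the intestinal phosphatase Alpi (-3.02 ± 0.56) fell. Mast cell markers rose in 5 of 6 (5 over the list alone, adjusted p = 6.9e-11, 0.0939 estimated), for example Mcpt4 from 0.0731 ± 0.0635 to 3.51 ± 1.59 CPM. Mcpt4 values with IFNa were near or below the floor, and the IgE receptor Fcer1a was 0 in every IFNa library, so no fold is given. Not every member was that low, since the summed mast cell markers had 5.37 to 12.1 CPM in IFNa libraries. Type I interferon genes rose in 2 of 36 (5 over the list alone, median 0.53, adjusted p = 8.7e-09, 0.290 estimated), Parp14 (1.12 ± 0.19) and Oasl2 (1.33 ± 0.27). T cell markers were higher with 0 members over all genes and 17 of 21 over the list alone (median 1.51, adjusted p = 2.7e-10, 0.290 estimated). Macrophage markers were higher with 0 and 17 of 21 (median 1.37, adjusted p = 2.0e-10, 0.290 estimated). Cd8a had 7.04 ± 3.34 and 19.96 ± 2.31 CPM (1.5 ± 0.43, adjusted p = 0.0906). Hypoxia genes were lower (median -0.49, adjusted p = 3.6e-06, 0.290 estimated, 7 of 21 over the list alone). Hepatoma genes were lower with Krt18 falling (-0.62 ± 0.10; list median -0.34, 0.290 estimated, -0.57 without combination replicate 1 and -0.22 without replicate 2).

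This count moved with the fit. Leaving out any 1 library gave 0 to 104 genes, and of 19 named genes that passed 0 did so without combination replicate 2, 2 without combination replicate 1 or 3, 5, 9 and 11 without IFNa replicates 3, 2 and 1. Of called genes 35.8% were higher, against 21.2% to 71.4% when 1 library was left out, 63.5% to 79.4% with limma on FPKM, 53.6% with DESeq2, 64.8% with a replicate block and 68.2% with only the groups compared. Non-overlapping values were found in 36.8% of genes (10% by chance), and 16 of 20 called lists kept their call without every single library.

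IFNa was compared with antiPD1 as the difference between single treatments, and 8 genes were higher and 7 lower in IFNa libraries. Jchain was lower with IFNa (1.92 ± 0.751 against 40.0 ± 17.6 CPM, log2 fold change -4.37 ± 0.42, adjusted p = 0.00682), as were Saa3 (1.90 ± 0.10 against 196 ± 242; -6.68 ± 0.96), the gut-homing integrin Itgb7 (-1.23 ± 0.19) and P4ha1 (92.0 ± 2.26 against 146 ± 8.84; -0.66 ± 0.10). Cyp2a4 (4.60 ± 0.69), the desmosomal protein Pkp1 (17.7 ± 1.16 against 7.74 ± 0.463; 1.20 ± 0.14) and the borate and proton carrier Slc4a11 (1.70 ± 0.23) were higher. B and plasma cell markers were lower in 11 of 11 members and also passed with an estimated correlation (median -2.61, adjusted p = 1.2e-19, 0.0397 estimated, 1 gene over all and 10 over the list alone). T cell markers were lower in 21 of 21 (0 over all and 20 over the list alone, median -2.12, adjusted p = 4.9e-16, 0.262 estimated, -1.33 without antiPD1 replicate 3). Macrophage markers were lower in 20 of 21 (0 and 19; median -1.56, 0.262 estimated, -0.73 without that library) and MHC class II genes in 11 of 11 (0 and 11; median -2.14, 0.262 estimated, -1.14 without it). With IFNa replicate 1 and antiPD1 replicate 3 both left out, the T cell and macrophage medians were -0.99 and -0.65. With the Y-linked level as a covariate they were -1.50 and -0.49, and both lists kept their call in both settings. Type I interferon genes did not differ at the threshold (median -0.16, adjusted p = 0.217), and the median was 0.09 with no call without antiPD1 replicate 3. Non-overlapping values were found in 22% of genes (10% by chance). The balance moved with the fit: 590 genes were higher and 1052 lower with DESeq2, 44 and 104 with a replicate block, 201 and 510 without antiPD1 replicate 1, and 40 and 7 without IFNa replicate 1. Leaving out 1 library gave 0 to 711 genes, with 0, 1, 1 and 2 of 12 named genes passing without IFNa replicate 2, IFNa replicate 3, antiPD1 replicate 2 and antiPD1 replicate 3.

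The interaction asked whether the effect of IFNa differed beside antiPD1. No gene passed: the smallest adjusted p was 0.158, for Pllp, with 40.0 ± 5.86, 25.3 ± 1.48, 19.6 ± 1.96 and 33.6 ± 4.02 CPM in untreated, IFNa, antiPD1 and combination libraries (interaction 1.44 ± 0.19). The Wnt inhibitors Notum (168 ± 72.2, 46.4 ± 14.2, 63.0 ± 12.6 and 125 ± 24.1; 2.84 ± 0.49) and Nkd1 (123 ± 31.1, 55.5 ± 2.02, 63.1 ± 17.4 and 113 ± 24.8; 1.98 ± 0.34) had the same shape, while Arg2 had an interaction of the opposite sign and was lowest in the combination (41.5 ± 1.22, 46.5 ± 4.60, 37.1 ± 3.99 and 22.5 ± 1.82; -0.89 ± 0.16). The DNA-binding inhibitor Id4 had 0.492 ± 0.0551, 1.44 ± 0.398, 2.14 ± 0.807 and 1.30 ± 0.195 CPM, and the deubiquitinase Usp13 was below the floor in untreated libraries. edgeR and limma called 0 genes (868 at an unadjusted p below 0.05) and DESeq2 called 55, of which 17 are pancreatic acinar genes found mainly in 4 libraries. Among lists, 29 of 29 cell cycle genes were positive (median 0.59, adjusted p = 2.2e-14, 0.647 estimated, 0.34 without IFNa replicate 1). So were 17 of 18 cholesterol genes (median 0.40, adjusted p = 5.7e-06, 0.647 estimated, 0.63 without IFNa replicate 1 and 0.19 without combination replicate 1). Hypoxia genes were negative in 19 of 21 (median -0.32, adjusted p = 9.1e-06, 0.647 estimated, -0.48 without untreated replicate 1 or antiPD1 replicate 3). Fibroblast genes were negative in 18 of 18 (median -0.79, adjusted p = 1.3e-06, 0.647 estimated; -0.50 and -1.38 without untreated replicates 2 and 3, -0.48 without antiPD1 replicate 3). These 4 of 18 called lists kept their call without every single library.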

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

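The tests in this part were chosen after the patterns were seen, except the comparison of T cell markers with Y-linked genes, whose thresholds were written before and whose wording was narrowed afterwards. Lists whose response to IFNa differed beside antiPD1 with the preset correlation had these interaction medians: cell cycle 0.59, fibroblast and matrix -0.79, cholesterol synthesis 0.40, hypoxia -0.32, cytotoxic effector -0.92, adult hepatocyte enzymes -1.59, adipocyte -1.60, T cell -0.96, alternatively activated macrophage -1.01, immediate early -0.45, TGF-beta and EMT -0.25, hepatocyte and hepatoma -0.38, B and plasma cell -0.82, endothelial -0.64, checkpoint -0.66, macrophage -0.54, neutrophil -0.83 and glycolysis -0.22. With an estimated correlation all 18 had an adjusted p of at least 0.647, and 10 lists passed without IFNa replicate 1 and antiPD1 replicate 3. Without antiPD1 replicate 3 alone, only 6 lists passed. Mast cell markers were among them (1.80, adjusted p = 0.0106), and these had not passed with all libraries. Calls lost without this library included checkpoint genes (0.13), macrophage markers (0.23), T cell markers (-0.23), adult hepatocyte enzymes (-0.04) and neutrophil markers (-0.17). B and plasma cell markers (-0.62, adjusted p = 0.0853), hepatocyte and hepatoma genes (-0.05) and cytotoxic effector genes (-0.40) lost the call too. So did alternatively activated macrophage genes (-0.66) and immediate early genes (-0.25). Calls were also lost for endothelial markers without antiPD1 replicate 1 (-0.25) and IFNa replicate 1 (-0.39), glycolysis genes without untreated replicate 3 (-0.08) and antiPD1 replicate 1 (-0.10), immediate early genes (-0.24), neutrophil markers (-0.42) and adult hepatocyte enzymes (-0.48) without IFNa replicate 1, cytotoxic effector genes without IFNa replicate 3 (-0.56), B and plasma cell markers without IFNa replicate 2 (-0.53), and TGF-beta and EMT genes without untreated replicate 2 (-0.15). Only 4 of the 18 lists kept their call without every single library.

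Genes of many immune cell types were higher with antiPD1 and with the combination than in untreated libraries, for example Cd8a, Jchain and Lyz2. A larger share of host cells in these samples is a candidate explanation, and the tests of it disagree. Summed T cell markers rose about as far as summed Y-linked genes. The log2 ratio of the sums moved by 0.0322 pooled SD with antiPD1 and by -0.102 with the combination. With 3 libraries per group and pooled SDs of 0.63 and 0.47 log2, this ratio cannot tell an equal rise from a somewhat different one. By medians of log2 fold changes, T cell markers rose further than the 4 Y-linked genes. These medians were 2.50 against 1.90 with antiPD1 and 1.90 against 1.52 with the combination. With the Y-linked level as a covariate the T cell list still passed with the preset correlation, at a median of 1.66 with antiPD1 (2.50 before) and 1.28 with the combination (1.90 before). None of its members passed, against 19 and 8 before, because the folds were smaller and their median standard error rose from 0.56 to 0.82 and 0.75. B and plasma cell markers stayed at 2.42 (2.53 before) and 1.72 (1.85 before), while macrophage markers fell from 1.80 to 0.58 and from 1.73 to 0.67. Whether host share is the whole cause is therefore left open. Y-linked genes measure it only if all hosts were of the same sex, which is not given in the sources used here, and 10 and 4 of 19 genes usually higher in male liver, a set chosen after its values were seen, rose in the same groups. An equal rise of every host cell type is argued against in the combination only with that limit. Endothelial markers moved by -6.76 SD against Y-linked genes (-1.62 and undecided with antiPD1), where the pooled SD in the combination was a small 0.12 log2. Fibroblast genes moved by -2.12 SD in the combination. Macrophage (1.16), neutrophil (0.82), mast cell (1.68) and adult hepatocyte (-0.83) ratios moved less. The ratio of T cell to endothelial markers, which needs no Y-linked gene, moved by only 1.81 SD (0.911 with antiPD1). The outlying library antiPD1 replicate 3 does not account for all of the T cell rise with antiPD1, since the T cell median was 1.71 without it. It carried much of the strength: without it 2 of 21 T cell markers passed (19 with all libraries). The macrophage median fell from 1.80 to 1.09, with 2 markers passing instead of 17. Over all genes 328 passed instead of 2126. Whether treatment drew immune cells in or the samples differed for other reasons stays open, and how much Y-linked signal comes from the hepatoma cells was not analysed here. Recruitment by antiPD1 is a hypothesis only.

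Hypoxia and HIF1 targets such as Vegfa, Ndrg1 and Slc2a1 were lower with the combination than with antiPD1. A single outlying library is argued against, since the median was -0.53 without antiPD1 replicate 3. With the Y-linked level as a covariate the median was -0.43. The 2 groups had similar Y-linked sums (log2 means 5.52 with antiPD1 and 5.31 with the combination), so the covariate had little to adjust. This test therefore cannot decide whether different host content plays a part. Less hypoxia or less HIF1 activity when IFNa was added to antiPD1 may explain the lower values. This is a hypothesis that these tests leave open, as are sample size and site of sampling. No single gene of this comparison passed over all genes.

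Crb3, C3, Gpr108, Trip10 and Nudt12, neighbours on chromosome 17, were higher in IFNa replicates 2 and 3 than in the 10 other libraries. A gain of this segment in the hepatoma cells of these samples may explain it, because the lowest deviation was 1.02 and the flanking genes stayed near 0 (medians 0.02 and -0.03). A response of these genes to IFNa is argued against, because the highest median among the 4 other libraries given IFNa was -0.0400. The interval was found by a search with thresholds chosen afterwards, and the gene thresholds left out leukocyte genes that follow Ptprc. DNA was not measured, so a shared origin of both samples with a gained segment remains a hypothesis. In log2 CPM the 2 libraries correlated at 0.993, the highest within any group, against 0.965 and 0.962 with IFNa replicate 1. By the chi-square of their counts per gene they were not the closest pair (27.6, against 14.2 for combination replicates 2 and 3). Whether the IFNa group holds 3 independent samples is therefore undecided, and the IFNa comparisons treat them as 3.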

How the results depend on the processing

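Settings that left libraries IFNa replicate 1 and antiPD1 replicate 3 out or used the Y-linked level as a covariate were chosen after the results were seen. The cause of each difference was not tested.

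Number of genes. For IFNa against untreated (0 genes) DESeq2 called 37 and leaving both libraries out 5; leaving out 1 library gave 0 to 3. For antiPD1 against untreated (2126) only the groups compared gave 0, DESeq2 3291, limma 977, 1063 with the 0.1 pseudocount and 785 without a filter, a 2-fold minimum 1348, both libraries out 1537 and the Y-linked covariate 1; leaving out 1 library gave 5 to 2705 (5, 6 and 328 without untreated replicates 1 and 2 and antiPD1 replicate 3). For the combination against untreated (1803) only the groups compared gave 3789, DESeq2 2979, limma 1015 and 1086, a 2-fold minimum 1038, both libraries out 4200 and the covariate 1; leaving out 1 library gave 33 to 2594 (81 and 116 without untreated replicates 1 and 2; 207, 143 and 33 without combination replicates 1, 2 and 3). For the combination against IFNa (137) only the groups compared gave 1132, DESeq2 1661, the replicate block 542, a 2-fold minimum 69, both libraries out 1305 and the covariate 23; leaving out 1 library gave 0 to 104 (55 and 25 without IFNa replicates 2 and 3; 7, 0 and 3 without combination replicates 1, 2 and 3). For the combination against antiPD1 (0) DESeq2 called 15, and leaving out 1 library gave 0. For IFNa against antiPD1 (15) no filter gave 4, only the groups compared 0, DESeq2 1642, the block 148, limma 1 with either pseudocount, a 2-fold minimum 9, both libraries out 43 and the covariate 2; leaving out 1 library gave 0 to 711 (47, 0 and 1 without IFNa replicates 1, 2 and 3; 711, 1 and 2 without antiPD1 replicates 1, 2 and 3). For the interaction (0) DESeq2 called 55 and both libraries out gave 2; leaving out 1 library gave 0 to 1. It could not be fitted to only the groups compared.

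Number of lists. An estimated correlation called 0 of 14 for IFNa, 0 of 22 for antiPD1 and 0 of 25 for the combination against untreated, 0 of 20 for the combination against IFNa, 1 of 21 for the combination against antiPD1, 1 of 18 for IFNa against antiPD1 and 0 of 18 for the interaction. fry called 0, 18, 15, 2, 0, 2 and 0 in the same order. The covariate called 6, 23, 21, 23, 15, 24 and 7, and both libraries out 16, 22, 25, 22, 17, 22 and 10. Leaving out 1 library gave 9 to 16, 21 to 23, 23 to 25, 19 to 22, 17 to 27, 18 to 23 and 6 to 27.

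Lists with these settings. With the covariate the type I interferon median was 0.15 (adjusted p = 0.0288) for antiPD1 against untreated, 0.67 with 0 of 36 genes passing for the combination against untreated, 0.31 for the combination against IFNa and 0.18 with a call (adjusted p = 0.00987) for IFNa against antiPD1, and glycolysis genes were -0.14 and lost the call (adjusted p = 0.134) for the combination against untreated. Macrophage markers were 0.65 for the combination against IFNa. With both libraries out, T cell markers gained a call for IFNa against untreated (0.72, adjusted p = 1.1e-07).

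Reversed values. With the covariate, endothelial markers were -0.20 and adult hepatocyte enzymes -1.63 for antiPD1 against untreated, the macrophage receptor Mrc1 -0.19 and the lipoprotein Apoa2 -0.30; adult hepatocyte enzymes were -1.34 for the combination against untreated, and fibroblast genes -0.36 for the combination against IFNa. Checkpoint genes in the combination against antiPD1 (-0.33 with all libraries) were 0.30 without antiPD1 replicate 3 and 0.30 with both libraries out. Without antiPD1 replicate 1 the checkpoint median kept its direction, at -0.60. Adult hepatocyte enzymes were 0.75 in the interaction with both out. Of the checks of named genes 9487 gave the same call, 1390 a weaker one, 456 a stronger one, 146 a moved value and 2 a reversed one; of the list checks 1451 were the same, 444 weaker and 7 reversed.

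Whether the replicate numbers pair the samples is undecided. Correlations of the 18 same-numbered pairs had a median of 0.0577 (-0.304 to 0.503, with 8 over 0.1), against -0.0500 for other pairs. Of 12 libraries, 7 were closest to one with their own number.

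Over the 10933 genes of at least 5 CPM, the fold changes of antiPD1 and the combination correlated at 0.927 (0.881 over all genes), those of IFNa and the combination at 0.655 (0.564) and those of IFNa and antiPD1 at 0.692 (0.682).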

Other observations

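The gene sets in this part were chosen after their values were seen, so their counts describe these libraries and test nothing further. Genes usually higher in male mouse liver rose with antiPD1 in 10 of 19 tested members (median log2 fold change 5.0), for example the fatty acid hydroxylase Cyp4a12a (8.74 ± 2.11), and in 4 of 19 with the combination (3.39). Genes usually higher in female liver fell in 5 of 9 members in both comparisons (medians -2.06 and -4.62), among them Cyp2a4 and Cyp3a16. Many members were near the count floor in untreated libraries, so these medians depend on the prior count.

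Targets of Wnt signalling were lower in 15 of 16 members after IFNa with 0 passing (median -0.59), fell in 6 of 16 with antiPD1 (-0.55) and in 2 of 16 with the combination (-0.22). The Wnt inhibitor Nkd1 fell with antiPD1 by 0.96 ± 0.24 and was -0.12 ± 0.24 with the combination. The interaction median was 1.0 with 14 of 16 members positive and 0 passing. Squamous genes such as Ivl fell in 4 of 10 members and rose in 1 with antiPD1, fell in 5 with the combination, and fell in 3 for the combination against IFNa.

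Digestive enzyme genes of pancreatic acinar cells were found mainly in 4 libraries, untreated replicates 2 and 3 and combination replicates 1 and 2. Of 36 genes listed, 24 reached 1 CPM in any library. Of these 24, 20 (83.3%) were higher in each of the 4 libraries than in any of the 8 others. Summed over these 20 genes, the 4 libraries had 60.3, 35.1, 115 and 63.5 CPM in the order named, and the 8 others at most 1.82. The 20 genes were picked for this pattern, so the sums are no separate test of it. Their profiles in the 4 libraries correlated at 0.959 or more.

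The libraries were also regrouped, in all 10 splits of each pairwise comparison and in 100 splits for the interaction, all but the real one drawn at random. The real grouping gave 2126 genes for antiPD1 and 1803 for the combination against untreated, and the highest of the 9 other splits gave 126 and 0; for the combination against IFNa (137) and IFNa against antiPD1 (15) the highest other gave 0 and 0. In each of these, 1 of 10 splits reached the real count. For IFNa against untreated the highest other split gave 2 and for the combination against antiPD1 0. The real count was 0 in both, which every split reaches whatever the data, so the 10 of 10 carries no information. These 10 splits are too few for a share under 0.05. For the interaction the real count was also 0, so 100 of 100 splits reached it by definition, and the highest other gave 1.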
